A study of Zea mays with 5 samples.

How the data were processed

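The processed data analysed here are from 1 library of Derivative 3-3 young leaves. Per the labels' protocols, nuclei were digested with micrococcal nuclease, chromatin was precipitated with a rabbit antiserum against maize CENH3, the recovered DNA was treated with sodium bisulfite, and fragments of 180 to 400 bp including adapters were sequenced. Bisulfite turns unmethylated C into U, read as T, so a C in a read counts as methylated. The 4 RNA-seq libraries of the series (control and Derivative 3-3, seedling and young leaf) were not analysed here, and no comparison between groups was made.

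The deposited table gives, per the file headers, for each cytosine the chromosome, the strand base (C or G), the position, the context, the base after the C, the methylation level and the read counts. The authors' methylated read count and total read count are raw counts without normalization. The deposited methylation level is a fraction from 0 to 1, and it equalled methylated over total reads at every cytosine (0 differed by more than 1e-06). The column headed as C reads is therefore the total coverage. The table holds no cytosine with under 3 reads. Per the submitters' processing notes, CASAVA, BWA 0.6.1 and the maize build B73 RefGen_v3 were used, with no role stated. The methylation caller, trimming, removal of duplicates, treatment of reads that map to several places and the bisulfite conversion rate are not given in the sources used here. Positions are printed as the file gives them, and whether they count from 0 or 1 is not given in the sources used here. Reads without molecular identifiers are not independent molecules and 1 read covers several cytosines, so intervals from read counts cover counting error only. Much of a maize chromosome is repetitive, so unmapped repeats can leave gaps in the listed cytosines, and reads from other copies can enter the levels. The table does not separate reads by chromosome copy. A variant of the plant against the reference changes the context of a cytosine and can also be read as a change in methylation.

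Levels were computed as methylated over all reads at cytosines with at least 5 reads, 26750 of the 43778 listed, with a median coverage of 7. Windows of 10 kb were counted from the first listed position, and a window entered a test with at least 10 cytosines of each context compared. Intervals are Wilson 95% intervals on reads and percentile intervals over 10000 resamples of whole windows. Contexts and sub-contexts were compared by two-sided sign-flip permutation of paired window differences, the spread along the region by permuting cytosines with their reads among positions, and correlations by permutation, each with 100000 draws (10000 for alternatives, 2000 where single windows were left out). Correlations were also tested by every circular shift of the windows, 25 or 26 in number. Strands of CG and CHG dyads were compared by Fisher's exact test. Adjusted p-values are Benjamini-Hochberg within each family of comparisons. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The functions were tested on simulated counts at the real sites and depths. Each simulated cytosine was drawn independently, so reads shared by neighbouring cytosines are not covered by these tests. In 100 sets of 5107 CHG cytosines with no effect, p was 0.05 or less in 5% of sets for the sign-flip test, 18% for the spread along the region, and 7% when cytosines were exchanged only at equal coverage. With 200 of 1373 CG and 200 of 832 CHG dyads simulated at 95% against 5%, 79.5% and 91% were found, a share that holds only when so many differ at once. For correlations of simulated CG and CHG windows the share was 21% for r and 8% for rho.

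The design, the named windows (the 3 highest and 3 lowest by CG and by CHH level among windows with at least 50 cytosines of that context) and the alternatives were fixed before the data were examined. The alternatives were coverage minimums of 1, 3 and 10 (5 and 20 for the site distribution), unweighted site means, windows of 5 and 20 kb, leaving out the 1% deepest cytosines, single strands and leaving out the outermost 10 kb. Planned comparisons of genes and of transposons with the remaining sequence were not made, since no annotation of B73 RefGen_v3 was used here. The planned comparison of CHH by both following bases was replaced by one on the base after the C, the only one in the table. The CHH comparison on the base after the C, exchange at equal coverage, leaving out single windows, the 1 kb bins and leaving out CHH cytosines at 50% or more were added after the data were seen.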

Results

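DNA methylation was measured along 1 stretch of maize chromosome 9 in a single bisulfite-ChIP library from young leaves of Derivative 3-3, the maize material in which the series title places a de novo centromere. The chromatin was precipitated with an antibody against CENH3, the histone H3 variant that marks active centromeres. The reads therefore come from the precipitated DNA rather than from a sample of all leaf DNA. The series holds no library of unprecipitated DNA, so how much of the precipitate was background could not be measured. The deposited table lists 43778 cytosines between positions 4301438 and 4587776, a span of 286339 bp, each covered by 3 to 36 reads with a median of 5. The 26750 cytosines with at least 5 reads (61.1% of those listed) carried 225134 base calls and entered the comparisons. The remaining 17028 cytosines had 3 or 4 reads. The series also holds 4 RNA-seq libraries, from control and Derivative 3-3 seedlings and young leaves with 1 library in each group, and their expression values were not analysed here. With 1 methylation library there was no replicate and no control for any value below. The spread given is that between windows of the region, and p-values describe this library only.

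The first comparison was between the sequence contexts in which plants methylate cytosine, where H stands for A, C or T. CG cytosines were methylated at 86.5% (95% interval 81.8 to 89.7 from resampling 10 kb windows, 5728 cytosines) and CHG cytosines at 68.8% (64.9 to 71.9, 5107 cytosines). CHH cytosines were methylated at 2.04% (1.77 to 2.40, 15915 cytosines). CG and CHG methylation are copied after replication by maintenance methyltransferases, whereas CHH methylation must be set anew. The Wilson 95% intervals from read counts alone were narrower, at 86.2 to 86.8% for CG, 68.4 to 69.2% for CHG and 1.96 to 2.11% for CHH, and cover counting error only. Over the 25 windows of 10 kb with at least 10 cytosines of every context, CG exceeded CHG by 14.0 ± 8.7 percentage points (SD over windows) and did so in 23 of 25 windows (sign-flip permutation test, two-sided, p = 1e-05, adjusted p = 1e-05 over 3 comparisons). CG exceeded CHH by 74.7 ± 23.2 and CHG exceeded CHH by 60.7 ± 17.0 percentage points, in 25 of 25 windows for both (permutation p = 1e-05 and adjusted p = 1e-05 for each). That p is the smallest that 100000 resamples can give.

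Individual CG cytosines were mostly near fully methylated, whereas CHG cytosines took a wider range of levels. Among cytosines with at least 10 reads, 85.7% of 1796 CG sites had a level of 80% or more (Wilson 95% interval 84.1 to 87.3), 10.4% lay between 20% and 80%, and 3.90% were at 20% or less (6.20% with a minimum of 5 reads and 7.37% with 20). Of 1642 CHG sites, 46.5% had a level of 80% or more (44.1 to 48.9), 44.2% lay between and 9.38% were at 20% or less. Of 4189 CHH sites, 97.9% were at 20% or less (97.4 to 98.3), and 2 sites (0.0477%) reached 80%. That last share was 0.145% with a minimum of 5 reads and 0.524% with 20.

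Methylation was not uniform along the region. Of the 21 windows with at least 50 CG cytosines, 14 were at 80% CG methylation or more, 5 lay between 50% and 80%, and 2 were below 50%. The highest levels lay side by side, at 94.0% for positions 4341438 to 4351437, 94.5% for 4351438 to 4361437 and 94.2% for 4361438 to 4371437 (Wilson 95% intervals 92.4 to 95.3, 93.5 to 95.4 and 93.6 to 94.8). The lowest were 34.9% for 4501438 to 4511437 (30.3 to 39.8, 65 CG cytosines) and 39.4% for 4491438 to 4501437 (36.6 to 42.4, 121 CG cytosines), followed by 72.7% for 4431438 to 4441437 (70.1 to 75.2). CHG was also low in those windows, at 42.7%, 33.6% and 54.1%. A pair of windows with under 50 CG cytosines, named after their values were seen, were lower still. CG stood at 16.3% at 4301438 to 4311437 (38 cytosines) and at 21.2% at 4521438 to 4531437 (18 cytosines), with CHG at 23.6% and 15.9%. Each of these 5 low windows held at least 1 stretch of 1 kb with CG at 5% or less.

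Among the 24 windows with at least 50 CHH cytosines, the 3 highest CHH levels lay near the left end of the region. They were 9.23% at positions 4321438 to 4331437 (Wilson 95% interval 7.96 to 10.7, 237 CHH cytosines), 4.84% at 4331438 to 4341437 (3.27 to 7.10) and 3.92% at 4311438 to 4321437 (3.24 to 4.73). A pair of sparser windows farther right, named after their values were seen, stood at 7.35% at 4401438 to 4411437 (4.04 to 13.0, 24 CHH cytosines) and 4.88% at 4411438 to 4421437 (1.35 to 16.1, 8 CHH cytosines). In the window from 4321438, 8 CHH cytosines at 50% or more, all between 4327364 and 4328533, carried 66 of 162 methylated CHH reads, and without them the level was 5.75% (4.73 to 6.97), still the highest of the 24. Without 11 such cytosines the window from 4311438 stood at 2.06% (1.58 to 2.69) and ranked 8 of 24, so its place rested on them, while the window from 4331438 held none. The lowest of the 24 windows with at least 50 CHH cytosines were 0.504% at 4501438 to 4511437 (0.196 to 1.29), 1.07% at 4341438 to 4351437 (0.702 to 1.63) and 1.21% at 4471438 to 4481437 (1.01 to 1.44).

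The spread between windows exceeded that from reassigning whole cytosines to random positions. The SD of window levels was 23.2 percentage points for CG, against a mean of 2.51 after permutation (p = 1e-05, adjusted p = 1.5e-05, 25 windows). For CHG it was 16.6 against 3.61 (permutation p = 1e-05, adjusted p = 1.5e-05, 26 windows), and for CHH 1.92 against 0.591 (permutation p = 0.00215, adjusted p = 0.00215, 26 windows). On simulated data without any difference between windows this permutation gave p of 0.05 or less in 18% of sets, because depth differs between windows, and in 7% when cytosines were exchanged only at equal coverage. Simulated cytosines were drawn independently, whereas neighbouring cytosines in the data share reads. These rates do not cover that, so the p-values of the spread may be too small. In 20 kb windows the SD for CHG was 9.42 percentage points, and with at least 10 reads that for CHH was 3.53 (permutation p = 0.0001 for both). With exchange at equal coverage, p was 0.0001 for CG, 0.0001 for CHG and 0.0009 for CHH (permutation test).

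**Figure D1:**
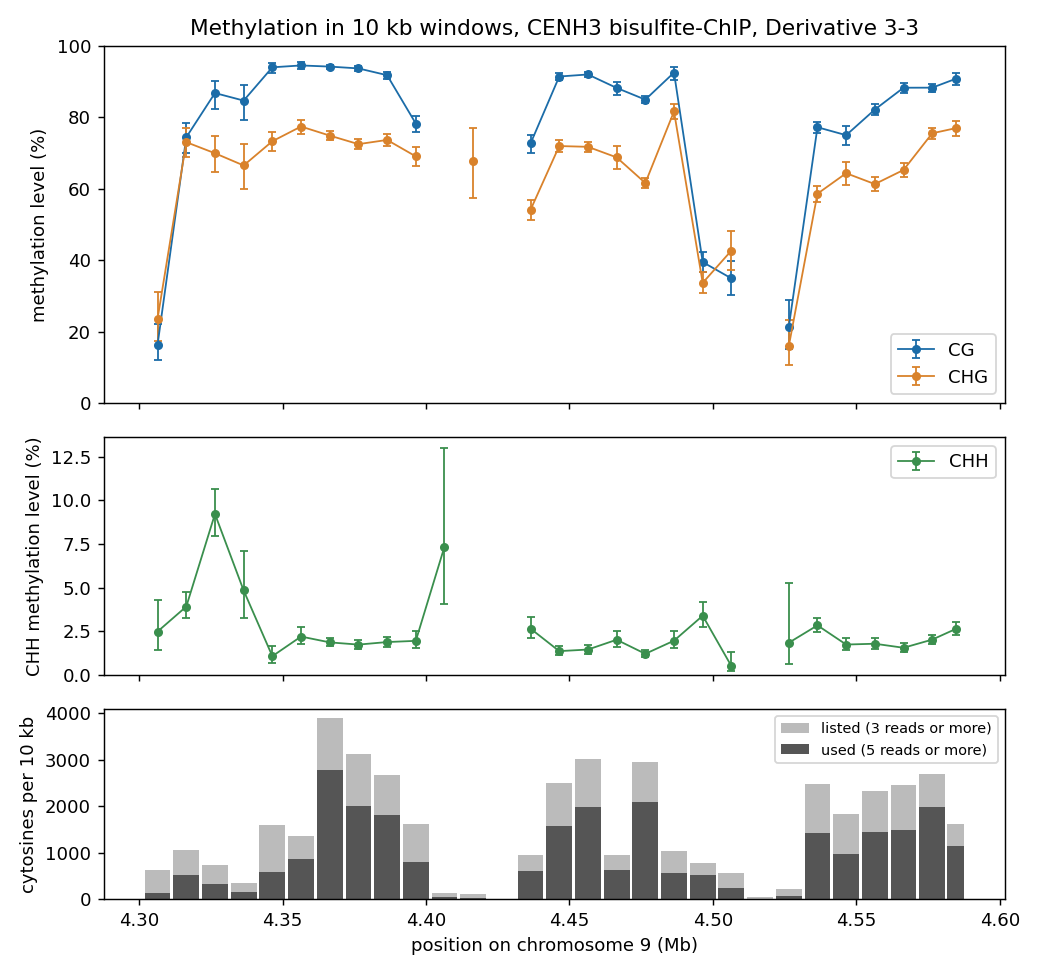
Methylation level (%) in 10 kb windows against position on chromosome 9 (Mb), for CG and CHG (top) and CHH (middle), with Wilson 95% intervals from read counts as error bars and only windows with at least 10 cytosines of the context shown. Bars (bottom) count the cytosines listed and used in each window (the last window is shorter); CG and CHG fall together in 4 windows while CHH peaks at 9.23% near the left end.

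CG and CHG methylation rose and fell together across windows, with Pearson r = 0.953 and Spearman rho = 0.848 over 25 windows (permutation p = 1e-05 for both, adjusted p = 3e-05 over 3 pairs). Circular shifts of one profile along the region, which keep neighbouring windows together, gave p = 0.04, the smallest that 25 shifts allow in this permutation. Without the 2 windows farthest from the median CG level, r was 0.899. No such relation was found for CHH. Its r was 0.03 with CG (rho -0.26, permutation p = 0.86 and 0.206, adjusted p = 0.86 and 0.309) and 0.05 with CHG (rho 0.02, permutation p = 0.812 and 0.923, adjusted p = 0.86 and 0.923). Without the 2 farthest windows these r were 0.0053 and 0.016. Among cytosines with at least 10 reads, which left 19 windows, r turned to -0.66 with CG and -0.52 with CHG (permutation p = 0.0055 and 0.0318). On simulated windows with no relation the permutation test of r gave p of 0.05 or less in 21% of sets and that of rho in 8%. Those cytosines were also drawn independently, so these shares do not cover reads shared by neighbouring cytosines.

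Within CHG, cytosines in CCG were methylated less than those in CAG or CTG. The level was 51.3% at 1452 CCG cytosines (95% interval over windows 46.9 to 54.7), against 76.2% at 1790 CAG cytosines (71.9 to 79.7) and 75.3% at 1865 CTG cytosines (70.7 to 78.7). CAG and CTG pair with each other on opposite strands, while the cytosine opposite a CCG lies in a CG. Window by window, CCG fell by 26.2 ± 9.6 percentage points (SD) relative to CAG and CTG and was lower in 22 of 23 windows (sign-flip permutation p = 1e-05, adjusted p = 2e-05 over 2 comparisons). Within CHH, the base after the cytosine also went with the level, at 3.24% for CA (2.80 to 3.84, 5594 cytosines), 1.81% for CT (1.53 to 2.14, 5294 cytosines) and 0.938% for CC (0.765 to 1.21, 5027 cytosines). CA exceeded the other CHH cytosines by 2.37 ± 2.28 percentage points and in 23 of 24 windows (permutation p = 2e-05, adjusted p = 2e-05). The difference was 1.49 percentage points when all listed cytosines were used (permutation p = 0.0004, 28 windows), and in 15 windows of 20 kb it was 1.38 and no longer passed the permutation test (p = 0.19).

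**Figure D2:**
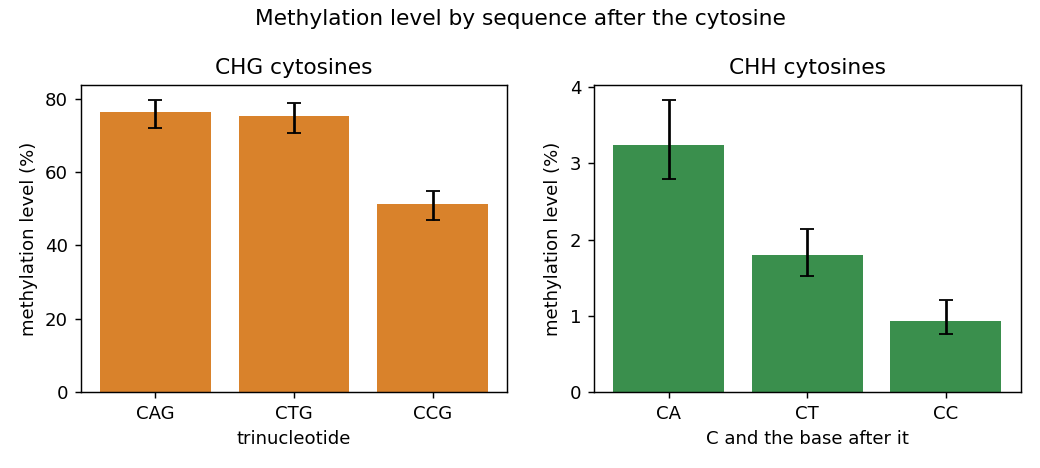
Methylation level (%) of CHG cytosines by trinucleotide (left) and of CHH cytosines by the base after the C (right), on separate axes that start at 0. Bars are levels over all reads and error bars are 95% intervals from resampling 10 kb windows; CCG stands at 51.3% against 76.2% for CAG and 75.3% for CTG, and CHH falls from 3.24% at CA to 0.938% at CC.

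Levels on the strands of a symmetric site were correlated across the region. Across 1373 CG dyads with at least 5 reads on both strands, the levels correlated with r = 0.703 and rho = 0.203, and 69.9% of dyads were at 80% or more on both strands while 4.44% were at 20% or less on both (permutation p = 1e-05 for r and rho). Across 832 CHG dyads, all of CAG paired with CTG, r was 0.631 and rho 0.434, with 45.0% high and 5.17% low on both strands (permutation p = 1e-05 for both). Dyads are sites of 1 library and not independent replicates. The permutation exchanges dyads along the whole region, so a level shared by neighbouring sites would also pass it. Neighbouring cytosines outside a dyad were not compared, so these values do not show symmetry beyond that of location. At a Benjamini-Hochberg adjusted p of 0.05, 0 CG and 0 CHG dyads differed between strands by Fisher's exact test, and 31 CG and 35 CHG dyads had an unadjusted p under 0.05. Dyads with one strand at 80% or more and the other at 20% or less numbered 2 for CG and 7 for CHG. A lone dyad would need an exact p of 3.64e-05 (CG) or 6.01e-05 (CHG) to pass the adjustment, which only 520 CG and 339 CHG dyads had the depth to reach even if fully opposite, so differences between strands were largely not detectable at this depth.

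Read depth varied along the region. The 29 windows held from 1 to 3900 listed cytosines with a median of 1369, and 5 windows held under 250. The longest stretches without any listed cytosine were the 9598 bp between positions 4507901 and 4517500 and the 9282 bp between 4423373 and 4432656. Windows with higher mean coverage had higher CG methylation (r = 0.50, permutation p = 0.0106, adjusted p = 0.0299, rho = 0.40, p = 0.0488, adjusted p = 0.0732) and higher CHG methylation (r = 0.45, permutation p = 0.0199, adjusted p = 0.0299, rho = 0.45, p = 0.0223, adjusted p = 0.0668). Circular shifts, which keep neighbouring windows together, gave permutation p = 0.12 for CG and 0.0769 for CHG. Without the 2 windows of most extreme coverage, r was 0.21 for CG and 0.41 for CHG, so the CG relation rested on those windows. With at least 10 reads per cytosine both relations were lost and turned, at r = -0.24 for CG and -0.05 for CHG (permutation p = 0.305 and 0.839, 19 windows), and in 20 kb windows that of CHG was lost (r = 0.36, permutation p = 0.184). Leaving out the window from 4301438 alone gave r = 0.36 for CG and 0.34 for CHG (permutation p = 0.086 and 0.087). CHH did not follow coverage by this test (r = -0.37, permutation p = 0.061, adjusted p = 0.061, rho = -0.17, p = 0.418, adjusted p = 0.418, circular shift p = 0.154, r = -0.21 without 2 windows). Its r was -0.19 without the window from 4401438 alone (permutation p = 0.386). It passed the permutation test in 20 kb windows (r = -0.55, p = 0.0386), without the 1% deepest cytosines (r = -0.43, p = 0.0273), without CHH cytosines at 50% or more (r = -0.45, p = 0.0171) and without any of 6 single windows (p from 0.018 to 0.0495). By depth of the cytosine, CG stood at 85.4%, 87.9% and 85.6% for 5 to 9, 10 to 19 and 20 or more reads. CHG stood at 69.2%, 68.1% and 70.2% in those classes and CHH at 2.0%, 2.02% and 2.89%, the last from 191 cytosines and 1.69% without CHH cytosines at 50% or more. The class of 20 or more reads held only 95 CG and 98 CHG cytosines. Without the 1% deepest cytosines it stood at 79.6% for CG, 66.2% for CHG and 3.15% for CHH.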

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

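The test of CA within CHH, leaving out CHH cytosines at 50% or more, exchange at equal coverage and leaving out single windows were chosen after seeing the data. A coverage minimum of 1 or 3 admits all listed cytosines and gave 85.0% for CG and 67.6% for CHG, while a minimum of 10 gave 87.7% and 68.4%. The unweighted CG mean was 86.0%. The forward strand alone gave 87.3% for CG, 70.3% for CHG and 1.88% for CHH, and the reverse strand alone 85.7%, 67.4% and 2.19%. CHH was 1.75% without cytosines at 50% or more. The share of CG sites at 80% or more was 79.9% at a minimum of 5 reads and 82.1% at 20, that of CHG sites was 50% at 20, and that of CHH sites at 20% or less was 96.5% at 5 and 97.4% at 20. These values lie outside the narrow counting intervals of the main ones but keep the order CG, CHG, CHH. Differences between CG, CHG and CHH (CG over CHG by 12.8 to 17.0 percentage points), the lower CCG level, the spread along the region in all contexts, the CG to CHG correlation (r 0.864 to 0.964) and the strand correlations stayed past the test under each alternative run for them, and when any single window was left out of those computed on windows. The CA difference within CHH was 1.49 percentage points at a minimum of 1 or 3 reads and 1.38 in 20 kb windows (permutation p = 0.19), and the cause was not tested. With at least 10 reads, r of CHH was -0.657 with CG and -0.525 with CHG, and r of coverage was -0.241 with CG and -0.050 with CHG. That setting left 19 windows, so fewer cytosines and windows entered, and the cause was otherwise not tested. In 20 kb windows r of coverage was 0.365 with CHG (permutation p = 0.184) and -0.546 with CHH (p = 0.0386). The CHH relation also passed without the 1% deepest cytosines (r = -0.426) and without CHH cytosines at 50% or more (r = -0.453), and when any of 6 single windows was left out, with r between -0.45 and -0.38 (permutation p from 0.018 to 0.0495), but fell to -0.194 without the window from 4401438 (permutation p = 0.386). With at least 10 reads it was 0.235 (permutation p = 0.347). The alternatives for genes were not run, as that comparison was not made. Single cytosines were shallow, at a median of 7 reads, and most dyads were too shallow for a difference between strands to pass.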

Other observations

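The 1 kb bins and the high CHH cytosines were chosen after the data were seen, and the tests of the base next to a high CHH cytosine, of the number of low bins expected by chance, of clustered against other high CHH cytosines and of the deepest low bin were chosen only after the result was seen. At 1 kb, the region was mostly densely methylated with a few bins almost free of methylation in every context. Of 179 bins with at least 5 CG cytosines, 153 were at 80% CG or more, 12 between 50% and 80%, 5 between 5% and 50%, and 9 at 5% or less. The 9 bins held 16 methylated of 1477 CG reads. Among them, positions 4504438 to 4505437 had 0 of 223 CG reads methylated over 39 cytosines, 4309438 to 4310437 had 0 of 121 over 24 cytosines, and 4493438 to 4494437 had 6 of 543 over 40 cytosines. Mean coverage there was 5.77, 5.02 and 13.3 reads per cytosine, in that order. Reads are counted at each cytosine, so 1 read can enter several times. The low 10 kb windows all contained a bin with CG at 5% or less. Without such bins, CG in the window from 4501438 went from 34.9% to 97.1% (21 cytosines left), in that from 4491438 from 39.4% to 77.9%, and in that from 4301438 from 16.3% to 39.1% (14 cytosines left). The bins were picked for low CG, so part of these rises follows from the choice. CHG, which did not itself enter the choice, went from 42.7% to 67.4%, from 33.6% to 58.9% and from 23.6% to 36.2%. CG and CHG cytosines of a bin can share reads, so the choice by CG can raise these CHG levels too. Without the 9 bins the SD between windows was 11.6 percentage points for CG (24 windows) and 9.14 for CHG (25 windows). Both were still above permuted cytosines at equal coverage (permutation p = 0.0001 for both, the smallest that 10000 draws can give). That permutation does not account for reads shared by neighbouring cytosines. The window from 4521438 dropped out, with 5 CG and 6 CHG cytosines left. Leaving out that window alone lowered the SD from 23.2 to 20.5 for CG and from 16.6 to 13.8 for CHG. Part of the fall in SD thus comes from its loss.

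Low depth as the source of these unmethylated bins is argued against only where a bin holds at least 5 independent reads. With 5 in each of the 179 bins chance would give 0.00802 such bins, and 9 were seen. Fewer independent reads would give more such bins, and removal of duplicates is not given in the sources used here. Bins with a coverage near 5 may fall short, so low depth stays open for them. Such bins include those from 4309438 (coverage 5.02), 4398438 (5.04) and 4506438 (5, with 25 CG reads). The binomial chance per bin, at most 1.8e-22, treats calls from shared reads as independent and is small for any bin picked for low CG. Loss of CG sites by variants in the plant would leave CHG methylated, but CHG in the bins was 0.45% (95% interval over bins 0.053 to 1.12), against 70.7% in the other bins. Abundant reads from unmethylated organelle DNA would raise coverage. Over all 9 bins, coverage per cytosine with at least 5 reads stood at 0.943 times that of the other bins (0.682 to 1.23). This ratio was 1.57 in the bin from 4493438, where this explanation stays open, and 0.760 in the other 8 (0.659 to 0.865). The prediction was written for all listed cytosines. Leaving out those with under 5 reads can draw the ratio towards equal coverage. Those 8 are what is left without the deepest bin, so the choice itself lowers their ratio. A smaller number of reads from another unmethylated copy, and a difference between the copies of chromosome 9 in the plant, remain open and untested. Beyond variants in the plant and, for the high CHH cytosines below, broad CHH patches, no biological explanation was tested here or for the CHH patterns. The design has 1 group for this assay.

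Single cytosines that fail bisulfite conversion at an even rate would occur alike in all bins. CHH in the 9 unmethylated bins was 0.196% (3 of 1527 reads, 95% interval over bins 0 to 0.389, Wilson interval 0.0668 to 0.576), against 2.04% (1.81 to 2.30) in the other bins. Such failure thus leaves most of the mean CHH level of 2.04% unaccounted for. An unconverted read also shows its CG as methylated, so picking bins for low CG tends to leave such reads out. Failure of whole reads therefore remains open, as does failure that varies between places.

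At a level of 50% or more, 69 CHH cytosines (0.434% of CHH sites) carried 14.5% of all methylated CHH reads, and 63.8% of them were followed by A, against 34.2% of CHH sites below 20% and 54.1% of those from 20% to below 50% (Fisher's exact test of the highest against the middle class, p = 0.129). Around all 69, CHH cytosines 2 to 25 bp away on the same strand stood at 7.43% (95% interval 4.33 to 10.9). Those 26 to 200 bp away on either strand stood at 4.40% (3.14 to 5.94). Both lay below the levels fixed before the test for unconverted reads and for broad CHH patches. Both also lay above the 2.04% of all CHH cytosines, so the test cannot tell whether either explanation holds. Around the 54 that lie fewer than 3 to a 1 kb bin these values were 2.66% (1.77 to 3.63) and 2.42% (1.91 to 3.06). Around the 15 in 3 bins they were 23.9% (14.4 to 31.2) and 14.6% (9.90 to 20.1), which include other high sites. The split was made by high sites nearby, so it lowers the former values and raises the latter, and it decides nothing about the cause. Both explanations stay open for the 69 sites, the 15 included. Without high sites the bins from 4327438, 4536438 and 4313438 stood at 8.57%, 8.97% and 0.997%. A candidate explanation for part of the set is a variant that makes the site a CG in the plant: of the 9 sites followed by C, which would then be the outer C of a CCG, 5 (55.6%) had a next base that was itself at 50% or more, against 24 of 5018 (0.478%) for other CHH sites followed by C (Fisher's exact test, p = 5.52e-10). Adjacent cytosines share reads, so unconverted reads or a local CHH patch could also give such pairs, and this test does not tell them apart. Some of these pairs lie in the 3 bins that hold those 15 sites. Across the 29 high sites with a used CHH cytosine just before them that cytosine stood at 20.8% (Wilson 95% interval 16.2 to 26.4), above the 0.938% of such sites and below the 51.3% of CCG. A CG-making variant at every high site is thus not what these values show, and the other high sites remain open. Of the 50 methylated reads of these preceding cytosines, 33 came from the 5 already at 50% or more. The other 24 stood at 8.81% (5.57 to 13.7), but they lie below 50% by that choice.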
